A study of Macaca fascicularis and Mus musculus with 42 samples.

How the data were processed

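The values are levels of genes in 42 bulk RNA libraries, made from the 3′ ends of transcripts starting from 1 ng of total RNA. There were 38 libraries from the cynomolgus monkey and 4 from mouse, in 1 table per species. The values were deposited as RPM, that is, the authors divided the reads of a gene by the total of the library, per the file names. Cutadapt 1.3, TopHat 1.4.1, Cufflinks 2.2.0 and the mouse build GRCm38 are named in the submitters' processing notes, without role or order. The genome build of the monkey table is not given in the sources used here, so no monkey coordinates are printed. The monkey table had 26018 entries, of which 9295 were unnamed LOC entries, and that of mouse 34896 besides 96 spike-in entries, which were not used in the tests.

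The low values of each library are whole multiples of a step, the RPM of 1 read. With a tolerance of 0.1 steps, 99.4% to 99.8% of the values up to 100 steps were whole in monkey and 99.6% to 99.8% in mouse, and reads per gene were recovered from this step. The 10 most abundant genes held 6.2% to 9.39% of the RPM in monkey libraries. Levels near 1 RPM rest on a few reads.

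Groups followed the labels: ESC of reporter lines, ESC of lines without transgenes, and sorted cells by gate, medium and day. Libraries within a group are numbered here in the order of the labels, which state neither replicate numbers nor separate cultures. The tests, thresholds, gene lists and the alternatives were fixed before the data were examined, except for those said to be chosen after seeing the data. Every test was made with limma 3.58.1 in R 4.3.3 as a moderated linear model on log2(RPM + 1), with an intensity trend, over genes with at least 10 RPM in at least 2 of the libraries in the fit. All groups of reporter lines were fitted together, so a group with a lone library borrowed its spread from the others. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 difference at least 1, or for the day trend a slope of at least 1 per 8 days. Gene lists were tested with camera from limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and the p-values were adjusted over the lists of a comparison. The 23 lists held 265 members, and 17 of these had no entry of their symbol in the monkey table. For some entries limma warned of sample variances of 0.

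Genes were named by a rule: PRDM1, TFAP2C, SOX17, NANOS3, POU5F1, NANOG and SOX2 in each comparison. To these came up to 4 members of each list described, those with the largest differences past the threshold. The 6 largest increases and 6 largest decreases past the threshold whose groups did not overlap completed the rule, without LOC entries. Genes under the filter were given as values alone. For a gene listed at 0 in all 4 ESC libraries, a fold was given as a lower bound against 3 reads over these libraries together.

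Reads of genes with near-identical copies could be split by the counting, which the labels do not describe, and strand was not used here. Alternatives were pseudocounts of 0.1 and 10, no filter, a mean of at least 20 RPM, median-of-ratios scaling, quantile normalization, a robust prior, the adjusted p alone, a log2 difference of at least 2, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, other sets of libraries, the title code as a covariate, and each library left out in turn. The sets without the 6 libraries whose PRDM1 level contradicts the gate, without the 9 whose group depends on the reading of the names (24 reporter-line libraries kept), without the 19 whose name differs between the readings, the MS134 libraries alone, and the series of title numbers as a block were chosen after seeing the data. In simulated data sized as GK15 day 6 against ESC, limma recovered 38.8%, 77.6% and 86.4% at log2 differences of 1.5, 2.5 and 4. There were 6 false calls. With the 24 libraries it recovered 50.7%, 76.1% and 97%. On such data edgeR recovered 150 and DESeq2 156 of the 200 changed genes. As labelled the real fit called 0, so this power does not apply. Among 703 pairs of monkey libraries none had identical columns, and the highest correlation was 0.978, between the libraries labelled GK15 BTAG day 6 library 1 and GK15 AG mid day 4 library 2.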

Results

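The libraries came from stem cells of the cynomolgus monkey (Macaca fascicularis) that were steered towards primordial germ cell-like cells (PGCLC), cultured counterparts of the founder cells of the germ line. RNA was read from the 3′ ends of transcripts in 42 bulk libraries, 38 from monkey and 4 from mouse, and the level of each gene was given in RPM, reads scaled to the total of the library. The reporter lines supplied 33 of the monkey libraries, and their cells carried tdTomato for PRDM1 (also called Blimp1) and EGFP for TFAP2C, both transcription factors of the early germ line. 5 of these were undifferentiated embryonic stem cells (ESC), 21 were induced cells sorted as BTAG positive, 3 as BT single positive and 4 as AG mid positive. BT is read here as the PRDM1 reporter and AG as the TFAP2C reporter, from the names in the labels. On days 2, 4, 6, 8 and 10 of induction there were 2, 2, 3, 2 and 2 BTAG positive libraries in GK15 medium, which contains serum replacement, and 2, 2, 4, 1 and 1 in aRB27 medium, which contains the B27 supplement. Another 5 ESC libraries came from lines without transgenes, and the mouse PGCLC gave 2 libraries on day 4 and 2 on day 6. Depth ranged from 1.07 to 7.42 M reads in the monkey libraries (median 2.28) and from 2.26 to 2.48 M in the mouse libraries. A single read thus stood for 0.134 to 0.929 RPM in monkey, and 12655 to 16052 genes were detected per library. The labels do not state that the libraries of a group are separate cultures, so every p-value measures the spread between these samples. Values are means ± SD in RPM, and log2 differences are given ± SE.

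The levels of the reporter genes were compared with the sorting labels before any other comparison. PRDM1 (102127621) lay between 85.1 and 318 RPM in 21 libraries sorted for its reporter and between 0 and 11.1 RPM in 6 ESC or AG mid libraries. The remaining 6 libraries of the reporter lines held the opposite level. PRDM1 was 0.50 RPM in the library labelled GK15 BTAG day 6 library 2, 4.9 in GK15 BTAG day 2 library 2 and 0 in GK15 BTAG day 4 library 2. It was 253 RPM in the library labelled reporter ESC library 5, 194 in GK15 AG mid day 2 library 1 and 145 in GK15 AG mid day 4 library 2. SOX17 (101925698), a transcription factor needed for germ cell fate in primates, was 1211 RPM in that ESC library and 3.98 RPM in that GK15 BTAG day 6 library. Reading the 33 names in alphabetical order would place 9 libraries, these 6 included, in another group. Each monkey comparison was therefore made with every library as labelled and also with the 24 libraries whose group is the same in both readings, a set chosen after seeing the data. Gene levels below come from the 24 libraries unless they are said to be as labelled.

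**Figure D1:**
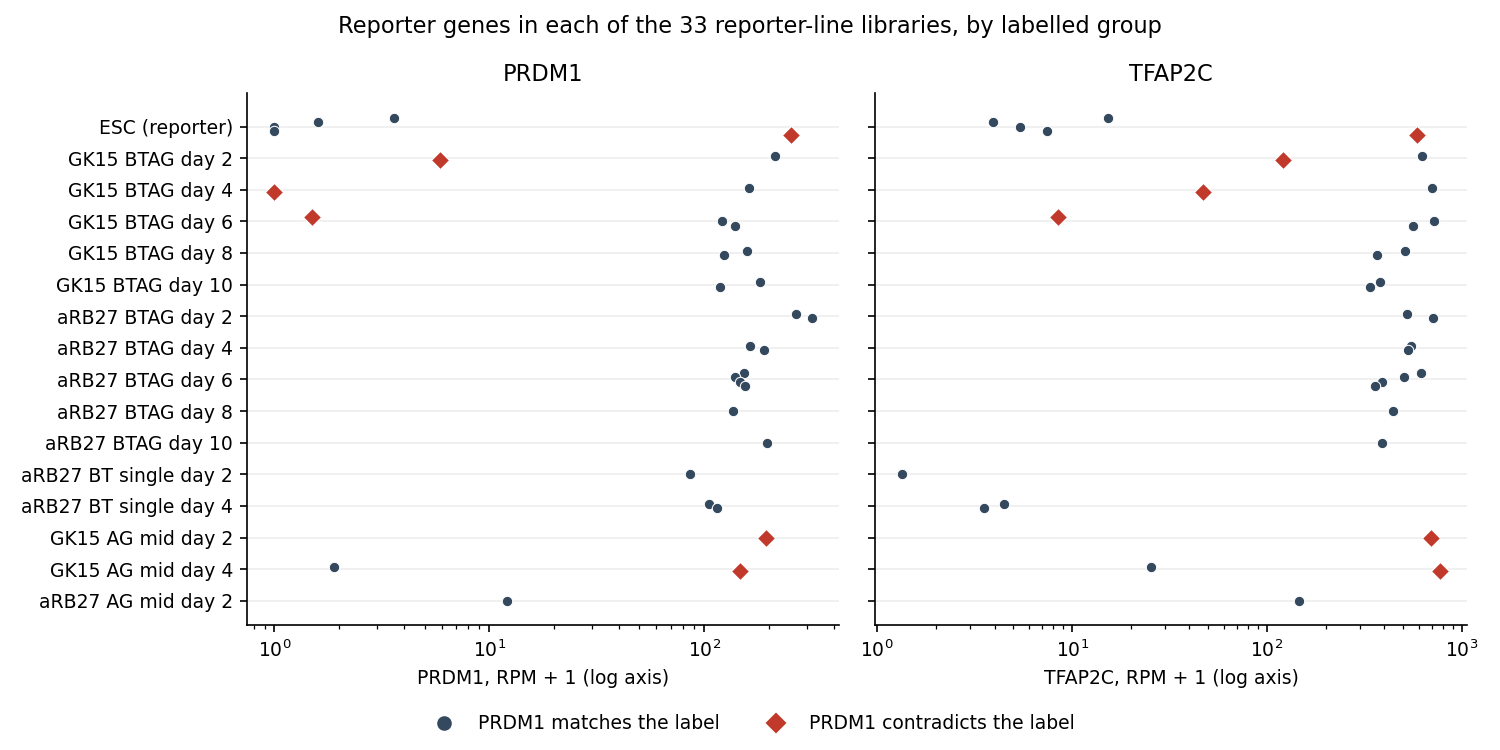
PRDM1 and TFAP2C levels (RPM + 1, log axis) of each reporter-line library by its labelled group, with the 6 libraries that contradict their label drawn as red diamonds. The 3 low diamonds in the BTAG groups have 0 to 4.9 RPM of PRDM1, and the 3 high ones in the ESC and AG mid groups have 145 to 253 RPM.

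The BTAG positive cells of day 6 were compared with ESC to describe the induced cells, separately in each medium. In GK15, germ cell genes that were near 0 in ESC became abundant, among them SOX17 (946 ± 163 against 1.71 ± 1.97 RPM) and KIT (349.8 ± 123 against 1.21 ± 1.4 RPM), which encodes the receptor for stem cell factor. NANOS3 (102133760), an RNA-binding protein that protects germ cells, was listed at 0 in all 4 ESC libraries and at 55.1 ± 7.29 RPM in GK15 and 39.2 ± 5.05 RPM in aRB27. It was at least 242-fold and 172-fold higher (floor of 3 reads over the 4 ESC libraries together, counting error only). The highest-ranked increases in GK15 were HPGD (1294 ± 221 against 0.182 ± 0.219 RPM), an enzyme that breaks down prostaglandins, and CRHBP (574 ± 23.8 against 0.537 ± 0.566 RPM), which binds corticotropin-releasing hormone. EFEMP1, a matrix glycoprotein, was at least 2189-fold higher. SOX2 (102140202), a pluripotency and neural factor, fell from 355 ± 38.7 to 1.14 ± 0.757 RPM in GK15 and to 11.5 ± 2.29 RPM in aRB27 (n = 2, 3 and 4 for GK15, aRB27 and ESC). SFRP1, a secreted WNT antagonist, and B2M, the light chain of MHC class I, fell in GK15, with log2 differences of -8.09 ± 0.82 and -7.37 ± 0.40 (limma adjusted p = 3.37e-07 and 1.33e-10). SPP1, which encodes osteopontin, FST, an activin antagonist, and GPC4, a surface proteoglycan, fell too in GK15, to 11.7 ± 4.77, 0.415 ± 0.587 and 1.02 ± 0.269 RPM. In aRB27 the largest increases besides SOX17 (646 ± 60.6 RPM) and HPGD (1136 ± 237 RPM) were those of DPP4, a surface peptidase (at least 1224-fold), SOSTDC1, a BMP antagonist, COL2A1, a collagen, and ST8SIA6, a sialyltransferase, at 248 ± 93.8, 709.5 ± 185 and 220.3 ± 6.47 RPM. The largest decreases in aRB27 included TAGLN, an actin-binding protein, and CD24, a surface glycoprotein, to 5.83 ± 5.59 and 13 ± 10.2 RPM. POU5F1 (102115117), a core pluripotency factor, rose from 791 ± 202 to 2792 ± 837 RPM in GK15 and to 3454 ± 852 RPM in aRB27. NANOG (102114964) was 240.1 ± 58.2 RPM in ESC, 595 ± 68.5 in GK15 (log2 1.33 ± 0.39) and 547 ± 108 in aRB27 (log2 1.19 ± 0.34). Its call in GK15 was lost without GK15 BTAG day 6 library 1 (log2 1.21) or GK15 BTAG day 6 library 3 (log2 1.45). PRDM1 and TFAP2C (102127991) were 129 ± 13.1 and 639 ± 111 RPM in GK15, a difference that the sorting gate itself sets.

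The gene lists moved as follows on day 6. Of the primate germ cell list, 11 of 13 measured members rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.21e-08 upwards) in GK15. In aRB27, 12 of 13 measured members rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 9.59e-11 upwards). The member that fell in both media was PRDM14, to 28.8 ± 0.141 and 32.3 ± 4.69 RPM from 142 ± 18.6 in ESC. It is a transcription factor required for mouse germ cells. Of the primed epiblast and neural bias list, 2 of 14 measured members rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 3.11e-05 downwards, adjusted p = 0.078 with an estimated correlation) in GK15. ZIC2, a neural factor, fell (21.4 ± 2.13 against 389.9 ± 83.5 RPM), whereas OTX2 and SALL3, both transcription factors, rose (72.1 ± 3.98 and 88.7 ± 12.9 RPM). In aRB27, 2 of 14 measured members rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.000436 downwards, adjusted p = 0.114 with an estimated correlation). For BMP targets in GK15, 7 of 9 measured members rose (7 and 0 adjusted over the list alone, camera adjusted p = 3.11e-05 upwards, adjusted p = 0.0583 with an estimated correlation), led by MSX2, a homeobox factor listed at 0 in ESC and at 72.3 ± 19.6 RPM in GK15. The aRB27 cells showed that 7 of 9 measured members rose (7 and 0 adjusted over the list alone, camera adjusted p = 1.1e-05 upwards). Of the naive pluripotency list, 2 of 3 measured members rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0259 upwards, adjusted p = 0.081 with an estimated correlation) in GK15, including TBX3 (92.1 ± 5.35 against 0.11 ± 0.22 RPM). In aRB27, 3 of 3 measured members rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.0103 upwards, adjusted p = 0.0608 with an estimated correlation). Of the shared pluripotency list, 2 of 7 measured members rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.852 upwards) in GK15. In aRB27, 3 of 7 measured members rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.477 upwards). Of the DNA and histone methylation list, 1 of 14 measured members rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0258 downwards, adjusted p = 0.081 with an estimated correlation) in GK15. Among them DNMT3B (57.8 ± 22.3 against 971 ± 219.5 RPM) and DNMT3A (7.76 ± 0.962 against 67 ± 11.7 RPM), the de novo DNA methyltransferases, fell. In aRB27, 4 of 14 measured members fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0252 downwards, adjusted p = 0.099 with an estimated correlation).

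Mesodermal and amniotic genes were also present on day 6. T (brachyury), a mesodermal transcription factor, rose from 3.31 ± 2.51 to 975 ± 224 RPM in GK15 and to 661 ± 105 RPM in aRB27. Of the primitive streak and mesoderm list, 5 of 12 measured members rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0259 upwards, adjusted p = 0.246 with an estimated correlation) in GK15. For the aRB27 cells, 5 of 12 measured members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0145 upwards, adjusted p = 0.194 with an estimated correlation). GATA3, a factor of amnion and trophoblast, rose from 1.74 ± 1.44 to 187 ± 13.7 and 169 ± 9.43 RPM, whereas VTCN1, a surface protein of the same list, fell from 39.3 ± 13.9 to 0 ± 0 RPM in both media. For the amnion and trophoblast list, 4 of 9 measured members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0131 upwards, adjusted p = 0.0692 with an estimated correlation) in GK15. In aRB27, 6 of 9 measured members rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00317 upwards). Of the endoderm list, 2 of 10 measured members rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.867 upwards) in GK15. Its median log2 difference was -0.13 and its mean was 0.03, which differ in sign. Of the proliferation list, 1 of 14 measured members rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.00516 downwards, adjusted p = 0.53 with an estimated correlation) in GK15. In aRB27, 9 of 14 measured members fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.000436 downwards, adjusted p = 0.299 with an estimated correlation). Both PLK1 (63.1 ± 7.29 against 246 ± 55.6 RPM), a mitotic kinase, and MKI67 (60.1 ± 10.5 against 172 ± 10.6 RPM), a marker of cycling cells, fell there. MCM2, which encodes a replication helicase subunit, rose in GK15 (514 ± 13.9 against 237 ± 33.6 RPM). Of the later germ cell list, 1 member was measured, PIWIL1, at 10.1 ± 5.75 RPM in GK15 and 15 ± 5.36 RPM in aRB27 against 5.67 ± 1.9 in ESC, where limma called it in aRB27. This call was lost without aRB27 BTAG day 6 library 1 (log2 1.02), aRB27 BTAG day 6 library 3 (log2 1.18) or reporter ESC library 1 (log2 1.09).

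With every library as labelled (n = 3 and 5), limma called 0 of 10937 genes between GK15 day 6 and ESC, 2062 had an unadjusted p under 0.05, and edgeR called 66 and DESeq2 299. The count became 1660 without GK15 BTAG day 6 library 2 and 242 without reporter ESC library 5, both with an opposite PRDM1 level. Among the 24 libraries (n = 2 and 4), 1493 genes rose and 1156 fell. SOX17 differed by 4.45 ± 2.17 on the log2 scale as labelled (limma adjusted p = 0.271) and by 8.81 ± 0.47 in the 24 libraries (limma adjusted p = 1.26e-10). It was called as labelled without GK15 BTAG day 6 library 2 (log2 6.97). In aRB27 (n = 4 and 5), 945 genes rose and 1134 fell as labelled, and 1372 rose and 1398 fell in the 24 libraries (n = 3 and 4). As labelled, 12 of 13 measured members rose (12 and 0 adjusted over the list alone, camera adjusted p = 5.5e-07 upwards, adjusted p = 0.36 with an estimated correlation) of the germ cell list in aRB27. In GK15, 0 of 13 measured members passed the test (4 and 0 adjusted over the list alone, camera adjusted p = 0.000217 upwards, adjusted p = 0.647 with an estimated correlation). The 2 media share their ESC libraries. Of 10701 genes, 1149 rose and 960 fell in both (mean 937 and 768 with these libraries divided). Independent lists would share 191 and 151. Simulated unchanged groups had almost no calls to share, but r between media was 0.38 (0.94 observed).

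Day 2, the earliest time sampled, was compared with ESC over the mean of both media. High already were SOX17 (1144 ± 41.6 against 1.71 ± 1.97 RPM) and NANOS3, at 16.4 ± 11.4 RPM (n = 3 and 4). PRDM1 and TFAP2C, which the gate sets, were at 266 ± 52.4 and 617 ± 92.2 RPM. Mesodermal, amniotic and BMP-responsive genes rose with them. T (brachyury) reached 299.6 ± 59.2 RPM, GATA3 (302 ± 30.7 against 1.74 ± 1.44 RPM) rose, and HAND1, a mesodermal and amniotic factor, was at least 709-fold higher. Of the primitive streak and mesoderm list, 7 of 12 measured members rose (9 and 0 adjusted over the list alone, camera adjusted p = 3.06e-06 upwards). For the amnion and trophoblast list, 6 of 9 measured members rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 5.8e-06 upwards). For BMP targets, 8 of 9 measured members rose (8 and 0 adjusted over the list alone, camera adjusted p = 2.29e-08 upwards), with ID1 (233 ± 32.4 against 40.7 ± 13.9 RPM) and ID2 (346 ± 109 against 46.5 ± 36.1 RPM), inhibitors of differentiation factors, among them. For WNT and NODAL targets, 5 of 9 measured members rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0018 upwards, adjusted p = 0.111 with an estimated correlation), including AXIN2, a feedback inhibitor of WNT signals (77.7 ± 28.4 against 10.3 ± 6.16 RPM). Of the germ cell list, 10 of 13 measured members rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 1.21e-05 upwards). Among the genes ranked by size, HPGD, PRPH, an intermediate filament, CALB1, a calcium buffer, and PCP4L1 rose, to 1246 ± 285, 820.0 ± 328, 285 ± 88.5 and 383 ± 191 RPM. SFRP1, S100A6, a calcium-binding protein, LDB2, a transcriptional cofactor, USP44, a deubiquitinase, and SPP1 fell, to 7.62 ± 7.17, 0.517 ± 0.488, 0.747 ± 0.903, 4.09 ± 3.38 and 112 ± 86.4 RPM. SOX2 was 21.8 ± 18.3 RPM. NANOG was 375 ± 128 RPM and did not pass (limma adjusted p = 0.228). POU5F1 was 1674 ± 403 RPM, and its call was lost without aRB27 BTAG day 2 library 2 (log2 0.94), reporter ESC library 1 (log2 1.09), reporter ESC library 3 (log2 1.05) or reporter ESC library 4 (log2 1.05).

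The day 2 counts depended on the libraries, and 1124 genes rose and 590 fell in the 24. As labelled (n = 4 and 5), 136 genes changed, 35 of which fell, and this count became 903 without reporter ESC library 5 and 23 without GK15 BTAG day 2 library 2. It was 0, 11, 2 and 20 without reporter ESC libraries 1, 2, 3 and 4, 8 and 9 without aRB27 BTAG day 2 libraries 1 and 2, and 2 without GK15 BTAG day 2 library 1. Rising genes were 65.6% of those called in the 24 libraries and 54.1% after quantile normalization, and 74.3% and 58.6% as labelled. The median of all genes went from 0.053 to -0.065 with it. T (brachyury) differed by 4.28 ± 1.83 as labelled (limma adjusted p = 0.208), and as labelled 0 of 9 measured members passed the test (8 and 0 adjusted over the list alone, camera adjusted p = 1.29e-05 upwards, adjusted p = 0.25 with an estimated correlation) of the BMP list.

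The change over days was tested as a slope in the BTAG positive cells, with the medium in the fit, to ask how the cells matured after day 2. TFCP2L1, a transcription factor of naive pluripotency and germ cells, went from 1.76 ± 1.98 RPM on day 2 to 104 ± 22.1 on days 8 and 10 (n = 3 and 4), and NANOS3 from 16.4 ± 11.4 to 75.7 ± 29 RPM, a slope of 0.34 ± 0.05 log2 per day. The day 2 means hold 2 aRB27 and 1 GK15 libraries and those of days 8 and 10 GK15 libraries only. In GK15 alone TFCP2L1 was 1.39 RPM on day 2 and 116 ± 26.4 on day 10, and NANOS3 7.44 and 87.9 ± 40.1. TCL1B, a cofactor of AKT signalling, DKK4, a WNT antagonist, and KYNU, a kynureninase, rose as well, to 120.5 ± 128, 247 ± 144 and 124 ± 46.4 RPM, as did BCL2L14 and SH2D4B (29.7 ± 18.5 and 80.5 ± 23.5 RPM). CER1, a secreted NODAL antagonist, fell from 297 ± 184 to 0 ± 0 RPM, CRABP2, a retinoic acid carrier, from 208 ± 87.3 to 2.62 ± 2.66, and B2M from 389 ± 73.6 to 4.91 ± 3.04. FREM1, a matrix protein, and CACHD1 also fell, to 0.463 ± 0.553 and 0 ± 0 RPM, and FN1, which encodes fibronectin, to 20.3 ± 21.4 RPM. The call of FN1 was lost without GK15 BTAG day 2 library 1 (log2 -0.58). For the germ cell list, 7 of 13 measured members rose (7 and 0 adjusted over the list alone, camera adjusted p = 1.37e-06 upwards, adjusted p = 0.173 with an estimated correlation). Of the proliferation list, 11 of 14 measured members fell (0 and 11 adjusted over the list alone, camera adjusted p = 1.16e-06 downwards, adjusted p = 0.255 with an estimated correlation), with PLK1 at 45.6 ± 21.4 against 159 ± 53 RPM. Of the p53 targets, 5 of 9 measured members rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 8.93e-05 upwards, adjusted p = 0.173 with an estimated correlation), with CDKN1A, an inhibitor of the cell cycle, at 76.3 ± 44.5 against 3.97 ± 5.71 RPM. Of the DNA and histone methylation list, 5 of 13 measured members fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.0318 downwards, adjusted p = 0.255 with an estimated correlation), with UHRF1, the cofactor of maintenance methylation, at 9.41 ± 4.18 against 42.8 ± 14.6 RPM and DNMT3B at 25.1 ± 5.93 against 159.9 ± 27.2. Of the primitive streak and mesoderm list, 6 of 10 measured members fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.0777 downwards), among them EOMES, a mesendodermal factor (1.49 ± 1.26 against 120.2 ± 16.6 RPM). SOX17, PRDM1 and TFAP2C had slopes of -0.12 ± 0.03, -0.10 ± 0.03 and -0.11 ± 0.03 per day, under the minimum set for a slope. So were those of POU5F1 and NANOG (0.06 ± 0.05 and 0.06 ± 0.04). SOX2 had a slope of -0.24 ± 0.12 (limma adjusted p = 0.14).

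In the day trend, 702 genes rose and 1202 fell in 15 libraries of the 24, and 689 rose and 1193 fell in the 21 as labelled. The share that rose depended on the scaling, at 36.9% on the RPM, 51.1% after median-of-ratios scaling and 52% after quantile normalization, and 36.6%, 48.1% and 51% as labelled. SOX17 passed the slope minimum without GK15 BTAG day 2 library 1 (log2 -0.14), GK15 BTAG day 4 library 1 (log2 -0.13), GK15 BTAG day 6 library 1 (log2 -0.12), GK15 BTAG day 8 library 1 (log2 -0.13) or GK15 BTAG day 10 library 2 (log2 -0.14), PRDM1 without GK15 BTAG day 10 library 1 (log2 -0.14) and TFAP2C without GK15 BTAG day 2 library 1 (log2 -0.14). SOX2 was called without aRB27 BTAG day 2 library 1 (log2 -0.33). Day 6 against day 4, the times also sampled in mouse, gave 17 genes that rose and 42 that fell over both media in the 24 libraries (n = 5 and 3), such as SH2D4B (53.1 ± 17 against 5.32 ± 3.07 RPM), which rose, and B2M (4.55 ± 3.08 against 34.6 ± 13.5 RPM), which fell. As labelled limma called 0 genes in that comparison, with 1069 at an unadjusted p under 0.05, against 0 with edgeR and 40 with DESeq2. It called 81 without GK15 BTAG day 4 library 1 and 3 without GK15 BTAG day 6 library 2. The count of 59 in the 24 libraries became 9 and 26 without GK15 BTAG day 6 libraries 1 and 3, 37 and 10 without aRB27 BTAG day 4 libraries 1 and 2, and 34 and 104 without aRB27 BTAG day 6 libraries 1 and 4.

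Each other day was also compared with ESC, medium by medium. KIT was 95.3, 214, 366 ± 39.9 and 411 ± 13.2 RPM on days 2, 4, 8 and 10 in GK15, with 1 library on each of days 2 and 4 and 2 on each of days 8 and 10, against 1.21 ± 1.4 in ESC. DNMT3B was 162, 90.8, 30.1 ± 1.83 and 20.1 ± 1.84 RPM on those days against 971 ± 219.5 in ESC. In GK15, 763 genes rose and 269 fell on day 2, 1053 and 593 on day 4, 1479 and 1430 on day 8, and 1663 and 1776 on day 10, with the lone libraries of days 2 and 4 assumed to vary like the other groups. The aRB27 cells had 1022 and 585 on day 2 and 1220 and 1024 on day 4. With the compared groups alone 234 of 477 genes called in GK15 fell on day 2 and 514 of 906 on day 4, so the balance of day 4 was reversed, as it was on day 8 (1165 and 1312) and on day 4 in aRB27 (931 and 961). As labelled the GK15 counts were 0 and 0 on day 2 (limma, 1339 genes at an unadjusted p under 0.05, 0 called by edgeR and 74 by DESeq2). They were 28 and 8 on day 4, 693 and 880 on day 8, and 1037 and 1372 on day 10. Those of aRB27 were 6 and 14, 167 and 220, 2 and 11, and 15 and 61 on the same days, the last 2 of which rested on 1 library each, assumed to vary like the other groups. Both are among the 9 libraries whose group depends on the order of the names. Without the 6 contradicted libraries, a set chosen after seeing the data, these were 1029 and 1067 on day 8 and 1098 and 1151 on day 10. As labelled edgeR called 0, 125 and 76 genes on days 2, 8 and 10 in aRB27 and DESeq2 127, 282 and 299. By edgeR more rose than fell on aRB27 days 4, 8 and 10 and GK15 days 8 and 10, opposite to limma. On GK15 day 4 edgeR called 246 and DESeq2 560. Quantile normalization moved the rising share from 77.8% to 52.3% on day 4 in GK15 as labelled, from 15.4% to 42.9% on day 8 in aRB27, and from 73.9% to 58.2% on day 2 in GK15 in the 24 libraries. The median of all genes stood at -0.11 on day 8 in aRB27 and -0.11 on day 10 in GK15 as labelled, and at 0.001 and -0.007 after median-of-ratios scaling. With quantile normalization the GK15 medians went from 0.067 to -0.075 on day 2 and from 0.062 to -0.061 on day 4 in the 24 libraries, and from 0.079 to -0.044 and from 0.048 to -0.066 as labelled.

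**Figure D2:**
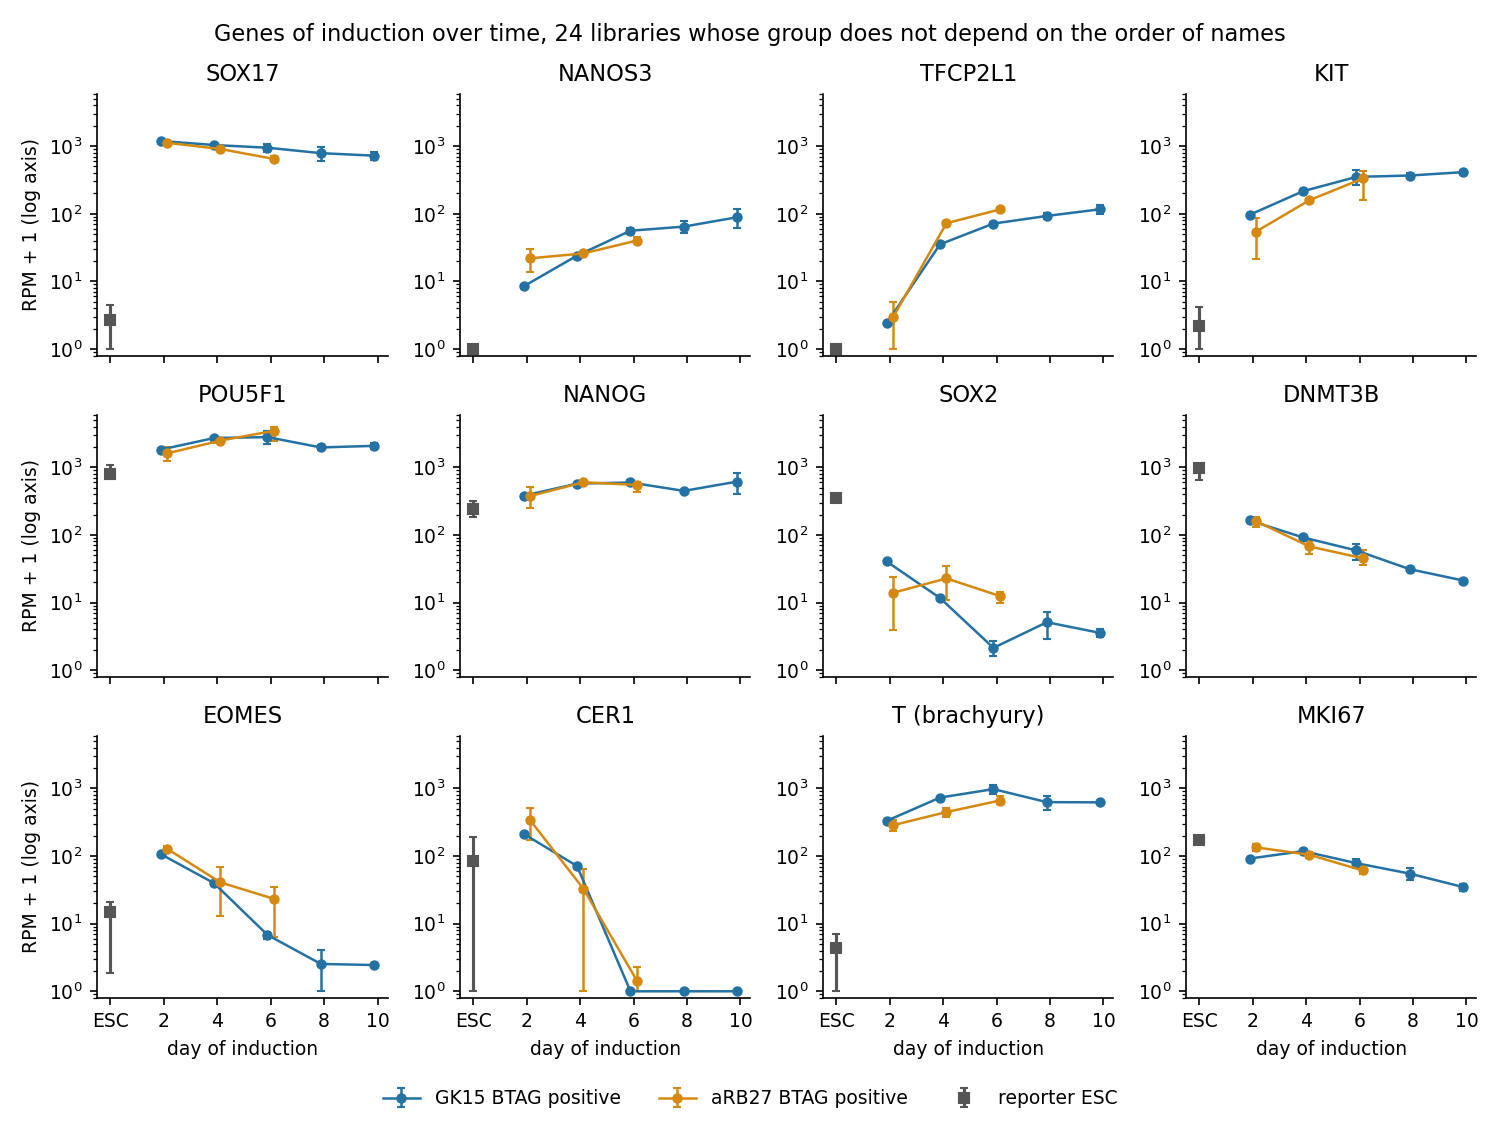
Levels (RPM + 1, log axis) of 12 genes in BTAG positive cells by day of induction in each medium, in the 24 libraries, with ESC at the left; points are means and bars span the lowest to the highest library. TFCP2L1 and NANOS3 climb with the days, while CER1 in GK15 goes from 212 RPM on day 2 to 0 ± 0 RPM on day 10.

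The media were compared within days to find what the basal medium changed in the BTAG positive cells. The 24 libraries hold no aRB27 library of days 8 and 10, so the difference rests on days 2 to 6. Most of the genes that differed were lower in aRB27. PTRF, a coat protein of caveolae, was 2.34 ± 1.66 RPM in aRB27 and 27.2 ± 15.2 in GK15 over days 2 to 6 (n = 7 and 4, log2 -2.87 ± 0.31, limma adjusted p = 0.000538). PDK4, which blocks pyruvate entry into the citric acid cycle, was 55.7 ± 16.1 against 200.4 ± 129 RPM. TXNIP, an inhibitor of thioredoxin and glucose uptake, and HK2, a hexokinase, were lower in aRB27 too (4.77 ± 2.62 and 12 ± 5.82 against 24.4 ± 7.55 and 42.8 ± 24.8 RPM), as were C5H4orf19 (3.07 ± 2.15 RPM) and MFGE8, a secreted lipid-binding protein (12.9 ± 6.1 RPM). FAM129A was higher in aRB27 (12.2 ± 7.77 against 2.13 ± 0.652 RPM). The germ cell factors did not pass the test between media, with log2 differences of -0.33 ± 0.15 for SOX17, 0.13 ± 0.28 for NANOS3, 0.05 ± 0.18 for POU5F1, -0.07 ± 0.20 for NANOG, 0.23 ± 0.14 for PRDM1, -0.29 ± 0.15 for TFAP2C and 0.87 ± 0.65 for SOX2. Of the immediate early and stress list, 1 of 8 measured members fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0214 downwards, adjusted p = 0.27 with an estimated correlation). The member was EGR1, an immediate early factor, at 222 ± 63.5 against 577 ± 155 RPM. For cholesterol synthesis, 0 of 13 measured members passed the test (0 and 0 adjusted over the list alone, camera adjusted p = 0.00294 upwards, adjusted p = 0.486 with an estimated correlation). For fatty acid synthesis, 0 of 8 measured members passed the test (0 and 0 adjusted over the list alone, camera adjusted p = 0.00367 upwards, adjusted p = 0.422 with an estimated correlation). On day 6 alone, HAPLN1, a matrix link protein, was 4.53 ± 3.15 against 44.8 ± 0.255 RPM, PDZK1, a scaffold protein, 29.8 ± 4.82 against 187 ± 34.2, and FAM20C, a secretory kinase, 37.5 ± 19.9 against 2.25 ± 0.233 (n = 3 and 2).

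Over days 2 to 6, 3 genes were higher and 45 lower in aRB27 in the 24 libraries, and 11 and 34 over days 2 to 10 as labelled. On day 6 alone, 4 were higher and 13 lower, and 1 and 5 as labelled. Without GK15 BTAG day 4 library 1 the count over days of 48 became 9, and TXNIP (-1.90), PDK4 (-1.69), HK2 (-1.72), EGR1 (-1.31), MFGE8 (-1.46), C5H4orf19 (-1.94) and FAM129A (2.07 on the log2 scale) lost their calls, while PTRF did not. Without GK15 BTAG day 6 library 1 or 3 the calls of TXNIP (-2.31 and -2.07), HK2 (-1.92 and -1.53), MFGE8 (-1.71 and -1.49) and FAM129A (1.81 and 1.69) were lost too. So were those of C5H4orf19 without GK15 BTAG day 6 library 3 (-1.84) or GK15 BTAG day 2 library 1 (-2.02), MFGE8 without aRB27 BTAG day 6 library 1 or 3 (-1.59 and -1.60), and FAM129A without aRB27 BTAG day 2 library 2, day 4 library 2 or day 6 library 1, 3 or 4 (1.89, 1.81, 1.89, 1.88 and 1.76). The count over days was 10 and 19 without GK15 BTAG day 6 libraries 1 and 3 and 79 without GK15 BTAG day 2 library 1. The day 6 count of 17 fell to 0 without either GK15 library, and to 2, 1 and 6 without aRB27 BTAG day 6 libraries 1, 3 and 4. HAPLN1, PDZK1 and FAM20C lost their calls without either GK15 library, PDZK1 also without these 3 aRB27 libraries in turn (-2.71, -2.65 and -2.48) and FAM20C without 1 or 3 (3.11 and 3.10). As labelled the day 6 count of 6 was 0 without aRB27 BTAG day 6 library 2, 3 or 4 or GK15 BTAG day 6 library 2 or 3. Genes higher in aRB27 were 6.25% of those called over the days and 21.1% after quantile normalization (24.4% and 36.2% as labelled), and 23.5% and 57.1% after median-of-ratios scaling on day 6, where that scaling moved the median of all genes from -0.12 to -0.008. As labelled that scaling moved the day 6 share from 16.7% to 100%. The slope per day differed between media for 14 genes in the 24 libraries, 5 with a higher and 9 with a lower slope in aRB27 (35.7% higher on the RPM and 46.7% after median-of-ratios scaling), and for 0 as labelled (limma, 567 at an unadjusted p under 0.05, and 0 with edgeR and 9 with DESeq2). The aRB27 libraries of the 24 stop at day 6. The count of 14 became 0 without aRB27 BTAG day 6 library 1 or 3, GK15 BTAG day 4 library 1 or GK15 BTAG day 10 library 1 or 2, and 1 without aRB27 BTAG day 2 library 1. It was 79 without aRB27 BTAG day 6 library 4, 42 without GK15 BTAG day 6 library 1, 9 without GK15 BTAG day 8 library 2 and 297 without GK15 BTAG day 2 library 1.

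BT single positive cells, sorted for the PRDM1 reporter alone, were compared with BTAG positive cells in aRB27 to see what PRDM1 marks outside the germ line. These cells expressed endodermal genes. Day 2 has 1 BT single library, so its calls rest on the spread of other groups and its gene lists are not given. On day 4, LHX1 and GATA6, transcription factors of mesendoderm and endoderm, were 573 ± 119 against 2.47 ± 2.67 and 403 ± 109.6 against 3.52 ± 2.34 RPM, and LGR5, a WNT-associated receptor, was 329.5 ± 328 against 0.625 ± 0.884 (n = 2 and 2). On day 2, TTR and APOB, genes of visceral endoderm and liver, were 778 and 344 RPM in the single library and 0 in both BTAG libraries, and FABP1, HNF4A and VTN were 675, 166 and 151 RPM and also 0 in both. NANOG fell to 4.46 ± 4.26 from 599 ± 30.6 RPM on day 4 and to 0.68 from 374 ± 181 on day 2, and POU5F1 to 195 ± 176 and 24.3 RPM. SOX17 was 821 ± 147 against 905 ± 63.6 RPM on day 4 and 475 against 1121 ± 15.6 on day 2, and passed the test on neither day (limma adjusted p = 0.903 and 0.358). Of the endoderm list, 8 of 10 measured members rose (8 and 0 adjusted over the list alone, camera adjusted p = 3.19e-06 upwards, adjusted p = 0.117 with an estimated correlation) on day 4. The same list gave as labelled that 5 of 11 measured members rose (7 and 0 adjusted over the list alone, camera adjusted p = 8.7e-07 upwards) on day 4. Of the germ cell list, 8 of 13 measured members fell (0 and 9 adjusted over the list alone, camera adjusted p = 3.62e-07 downwards) on day 4. TFCP2L1 was listed at 0 against 71.5 ± 9.03 RPM and NANOS3 was 3.1 ± 3.36 against 24.9 ± 1.8. On day 4, 8 of 12 measured members rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000576 upwards, adjusted p = 0.117 with an estimated correlation) of the streak and mesoderm list. GSC, an organizer factor, rose (88.1 ± 25.3 against 0 ± 0 RPM), while T (brachyury) fell (36.5 ± 35.7 against 446 ± 96.7). CRHBP, ADCYAP1, a neuropeptide, TMEM119 and ABCG1, a cholesterol exporter, fell on day 4, to 0 ± 0, 0.725 ± 1.03, 0.50 ± 0.707 and 0 ± 0 RPM, and SYNDIG1L rose to 201 ± 96.1. CBLN2, LYPD1, AP3B2 and RPRM fell on day 2, to 0, 1.47, 1.37 and 0.34 RPM.

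On day 4, 861 genes were higher and 758 lower in BT single positive cells in the 24 libraries and 249 and 154 as labelled. On day 2, 341 and 402, and 55 and 23 as labelled. The compared libraries are the same in both sets, and the spread estimated from the other groups differs. The as-labelled day 4 count of 403 became 81 and 89 without aRB27 BTAG day 4 libraries 1 and 2, and 206 and 51 without aRB27 BT single day 4 libraries 1 and 2. Without aRB27 BTAG day 2 library 2 the day 2 counts of 743 and 78 became 414 and 22. CER1 was 1649 ± 1010.0 against 31.8 ± 44.9 RPM on day 4, and its call was lost without aRB27 BTAG day 4 library 1 (log2 4.53) or aRB27 BT single day 4 library 2 (log2 6.86). SOX2 was 0.86 ± 0.198 RPM on day 4 and 0 on day 2, and NANOS3 was 1.71 on day 2. Their day 2 calls were lost without aRB27 BTAG day 2 library 2 (log2 -1.97) for SOX2 and aRB27 BTAG day 2 library 1 (log2 -2.33) for NANOS3. TFAP2C was 3.0 ± 0.672 and 0.34 RPM in the BT single cells, as the gate sets it, and PRDM1 was 109 ± 7.28 and 85.1, whose day 2 call was lost without aRB27 BTAG day 2 library 1 (log2 -1.89) or aRB27 BTAG day 2 library 2 (log2 -1.63).

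AG mid positive cells, sorted on an intermediate TFAP2C reporter signal, were compared with BTAG positive cells of the same day to describe cells of the aggregate outside the germ cell gate. In the 24 libraries day 4 has 1 library on each side and day 2 has 1 AG mid library against 2, so the calls and list tests below rest on the spread of other groups. On day 4 in GK15, CXCL12, a chemokine, was 1766 against 4.33 RPM, TGFBI, a matrix protein, 1577 against 5.33, and RGS5, a regulator of G protein signals, 994 against 0.67. RGS4, LIX1 and IGFBP5 were also higher there (351, 373 and 289 RPM). On day 2 in aRB27, CXCL12 was 1227 against 10.3 ± 13.7 RPM, BMP4, the ligand also supplied in the medium, 295 against 0.485 ± 0.686, and CLDN10, a tight junction protein, 480.3 against 7.84 ± 10.3. SOX17 was 4.63 against 1037 RPM on day 4 and 114 against 1121 ± 15.6 on day 2, and NANOG 0.75 against 572 and 14.4 against 374 ± 181. POU5F1 was 75.9 against 2703 RPM on day 4, NANOS3 0.30 against 23 and T (brachyury) 1.94 against 730.5. On day 2 POU5F1 (792 against 1602 ± 541) and NANOS3 (4.13 against 20.9 ± 11.7) did not pass (limma adjusted p = 0.517 and 0.0997). SOX2 was 23.9 against 10.7 RPM on day 4 and 33.4 against 12.9 ± 14.1 on day 2 and passed on neither, but it was called on day 2 without aRB27 BTAG day 2 library 2 (log2 3.13). Other genes that fell were CRHBP, MGLL, a monoglyceride lipase, and WNT16 on day 4 (0.45, 0.15 and 0.15 RPM) and FGFBP3, NMU, a neuropeptide, IL6R, CALB1, OTX2 and CHL1 on day 2 (1.65, 2.06, 0, 3.3, 0 and 0.83 RPM). For the amnion and trophoblast list, 5 of 9 measured members rose (6 and 0 adjusted over the list alone, camera adjusted p = 5.91e-05 upwards) on day 4. On day 2, 4 of 9 measured members rose (5 and 0 adjusted over the list alone, camera adjusted p = 5.55e-05 upwards). For BMP targets, 4 of 9 measured members rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.000112 upwards) on day 4. On day 2, 4 of 9 measured members rose (7 and 0 adjusted over the list alone, camera adjusted p = 4.87e-09 upwards). Of the germ cell list, 7 of 13 measured members fell (0 and 11 adjusted over the list alone, camera adjusted p = 3.51e-12 downwards) on day 4. On day 2, 2 of 13 measured members fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.000592 downwards).

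With every library as labelled, limma called 0 genes on day 4 (n = 2 and 2), with 176 at an unadjusted p under 0.05, 0 called by edgeR and 0 by DESeq2. It called 0 on day 2 as well (n = 2 and 4, both media), with 251 at an unadjusted p under 0.05, 0 called by edgeR and 4 by DESeq2. The AG mid libraries labelled day 2 library 1 and day 4 library 2 of GK15 had 1067 and 736 RPM of SOX17. In the 24 libraries 368 genes were higher and 512 lower on day 4 and 168 higher and 289 lower on day 2. By label the 2 libraries of day 4 have different title codes, MS134 and MS162, so gate and code cannot be separated there. Without GK15 BTAG day 4 library 1 the as-labelled day 4 count was 14, and without aRB27 BTAG day 2 library 1 the day 2 count of 457 in the 24 libraries was 237. TFAP2C was 24.4 and 146 RPM and PRDM1 0.90 and 11.1 RPM in the AG mid cells on days 4 and 2, a difference set by the gate. The day 2 call of TFAP2C was lost without aRB27 BTAG day 2 library 1 (log2 -2.27) or aRB27 BTAG day 2 library 2 (log2 -1.83).

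The reporter ESC were compared with ESC of lines without transgenes to ask whether the reporter lines differ at the start. Libraries count as replicates here, 3 of 656BTAG42 and 1 of 656BTAG63 against 5 of 4 lines, with CMK6 present 2 times. Several genes were close to 0 in the reporter ESC. ERP29, a chaperone of the endoplasmic reticulum, was listed at 0 in all 4 and at 67.2 ± 18.8 RPM in the 5 libraries of the other lines (limma adjusted p = 2.36e-06). SLC41A3, a magnesium transporter, was also listed at 0 against 19.2 ± 6.64 RPM, VAPB, a tether protein of the same organelle, was 0.0375 ± 0.075 against 43.7 ± 33, and INSR, the insulin receptor, 0.135 ± 0.27 against 14.3 ± 6.16. In the parental line 656 these genes were at 43.8, 21.6, 44 and 8.36 RPM in its single library. GJC1, a gap junction protein, was higher in the reporter ESC (53.1 ± 15.5 against 11 ± 1.23 RPM), as were ALG11, a glycosyltransferase, PHLDA1 and PHLDB2 (62.6 ± 15.3, 131 ± 29.7 and 46.6 ± 12.3 RPM). MAL2 and SERPINB6 were lower (2.76 ± 0.846 and 36.4 ± 12.5 against 53.1 ± 47 and 219.6 ± 108 RPM). POU5F1 (791 ± 202 against 1609 ± 209 RPM), NANOG (240.1 ± 58.2 against 444 ± 262) and SOX2 (355 ± 38.7 against 243 ± 130.3) did not pass the test (limma adjusted p = 0.122, 0.426 and 0.415). NANOS3 was listed at 0 in all libraries of both kinds. Of the primed epiblast list, 0 of 14 measured members passed the test (0 and 0 adjusted over the list alone, camera adjusted p = 0.0336 upwards, adjusted p = 0.507 with an estimated correlation). Of the hypoxia and glycolysis list, 1 of 10 measured members fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.156 downwards). It was ALDOA, a glycolytic enzyme. In all, 5 genes were higher and 14 lower in 4 reporter ESC libraries, and 5 and 11 with all 5 as labelled. The count of 19 was 6, 5, 12 and 7 without reporter ESC libraries 1 to 4, and 41, 6 and 9 without transgene-free ESC libraries 3, 4 and 5. Without reporter ESC library 2 or 4 or transgene-free ESC library 4, among others, ALG11 (1.67 to 1.97), PHLDA1 (1.59 to 1.62), PHLDB2 (1.44 to 1.69), MAL2 (-3.59 to -3.28) and SERPINB6 (-2.66 to -2.26) lost their calls, where the log2 ranges cover all fits in which the call was lost. INSR lost its call without reporter ESC library 2 (log2 -3.62), reporter ESC library 1 (log2 -3.62), transgene-free ESC library 2 (log2 -3.60) or transgene-free ESC library 4 (log2 -3.54), and ERP29, SLC41A3, VAPB and GJC1 kept theirs in every fit. With the CMK6 libraries averaged the count was 37. The 2 kinds of line share no title code, so line and title code cannot be separated here.

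Mouse PGCLC of day 6 were compared with those of day 4 in the same kind of medium, GK15. Rhox6 (19202, GRCm38 chromosome X, 37826910 to 37829857, plus strand) and Rhox9, X-linked homeobox genes of reproductive tissue, went to 562 ± 22.6 from 75.1 ± 36.3 RPM and to 755 ± 46 from 133 ± 74.4 (n = 2 and 2). Dnmt3l, a cofactor of de novo DNA methylation, and Piwil2, a protein of the piRNA pathway, rose to 12.1 ± 1.7 from 1.54 ± 1.56 and to 29.8 ± 10.7 from 5.74 ± 1.24 RPM. Rpl39l, BC048679, Calcoco2 and Rgcc rose to 44.8 ± 22.8, 218 ± 3.13, 121 ± 0.714 and 106 ± 17.2 RPM. Nkx1-2 (GRCm38 chromosome 7, 132594878 to 132599637, minus strand), a homeobox gene of the caudal epiblast, went to 0.62 ± 0.311 from 27.2 ± 17.8 RPM, Sox3, a neural factor, to 1.04 ± 0.905 from 28.3 ± 17.5, and Wnt5a, a secreted WNT ligand, to 1.45 ± 0.332 from 30.04 ± 9.36. Msx1os, Cxcl12 and Serpinf1 fell to 3.08 ± 0.205, 3.07 ± 1.37 and 1.66 ± 0.629 RPM. Of BMP targets, 3 of 7 measured members fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.000355 downwards, adjusted p = 0.423 with an estimated correlation). Of WNT and NODAL targets, 2 of 6 measured members fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.00093 downwards, adjusted p = 0.423 with an estimated correlation). Of the later germ cell list, 1 of 8 measured members rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.00093 upwards, adjusted p = 0.423 with an estimated correlation). Of the naive pluripotency list, 1 of 5 measured members rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.00135 upwards, adjusted p = 0.423 with an estimated correlation). For shared pluripotency, 3 of 10 measured members rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0267 upwards, adjusted p = 0.469 with an estimated correlation). For cholesterol synthesis, 0 of 11 measured members passed the test (0 and 0 adjusted over the list alone, camera adjusted p = 8.87e-06 upwards, adjusted p = 0.423 with an estimated correlation). Nanog was 353 ± 19.7 against 249 ± 14.8 RPM, Pou5f1 691 ± 184 against 817 ± 104, Sox2 389 ± 6.68 against 442 ± 33.9, Nanos3 10.7 ± 0.297 against 16.8 ± 3.13, Prdm1 118 ± 13.3 against 149 ± 11 and Tfap2c 236 ± 2.75 against 287 ± 16.7, all under the log2 minimum of 1. In all, 99 genes rose and 115 fell by limma, edgeR called 244 and DESeq2 138. The 214 calls became 62 without mouse day 4 library 1, 0 without mouse day 6 library 1 and 0 without library 2, and 0 without the filter on low values. The rising share was 46.3% on the RPM and 56.5% after quantile normalization.

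Levels of germ cell genes in mouse and monkey PGCLC of day 6 were set side by side without a test, from tables normalized separately. Sox17 (20671, GRCm38 chromosome 1, 4490931 to 4497354, minus strand) was 0.21 ± 0.297 RPM in mouse, and SOX17 was 946 ± 163 in monkey GK15 and 646 ± 60.6 in aRB27 (n = 2, 2 and 3). Sox2 went the other way, with 389 ± 6.68 RPM in mouse against 1.14 ± 0.757 and 11.5 ± 2.29 for SOX2 in monkey. Dppa3, which protects maternal methylation marks and carries a reporter in this mouse line, was 685 ± 204 RPM in mouse, and DPPA3 was 0.30 ± 0.424 and 0.14 ± 0.242 in monkey. Prdm14 was 109.7 ± 10.9 RPM in mouse, with PRDM14 at 28.8 ± 0.141 and 32.3 ± 4.69 in monkey. Prdm1 (118 ± 13.3 RPM) and PRDM1 (129 ± 13.1 and 145 ± 6.81) lay closer together, as did Tfap2c (236 ± 2.75) and TFAP2C (639 ± 111 and 502 ± 115). The gates set PRDM1 and TFAP2C in monkey and may set Prdm1 in mouse (BV).

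**Figure D3:**
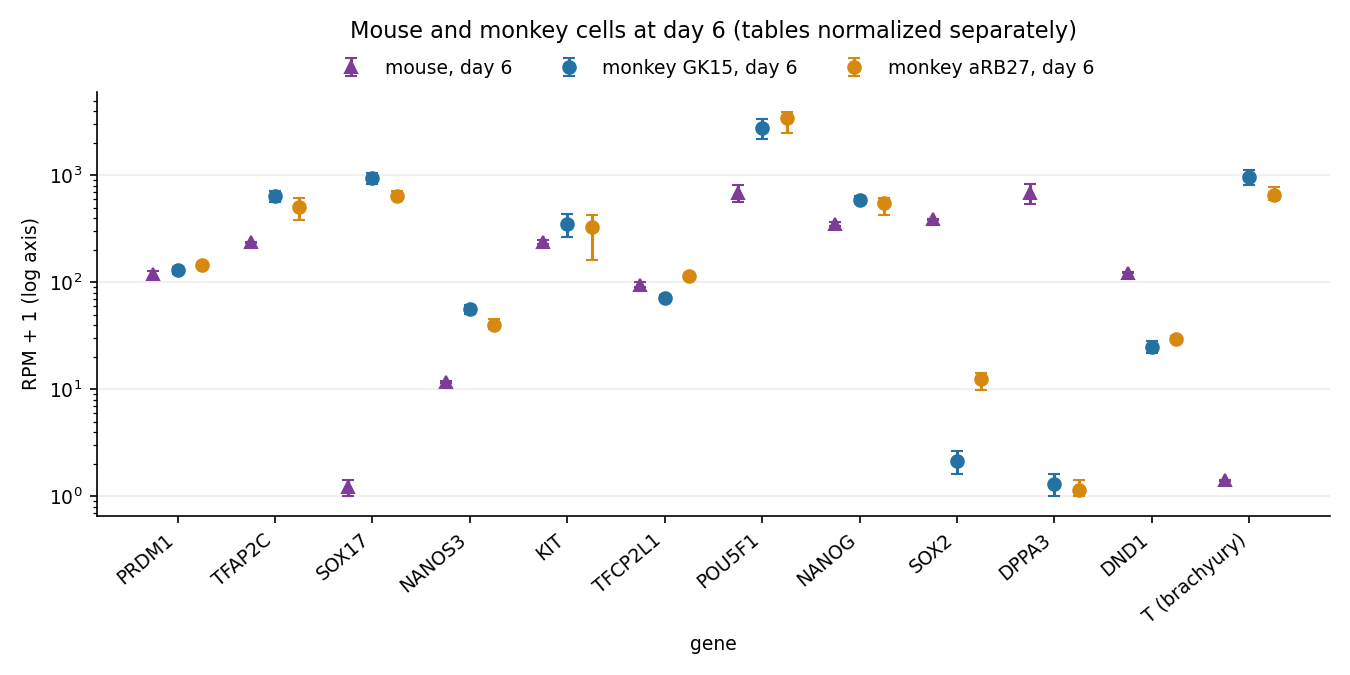
Levels (RPM + 1, log axis) of 12 germ cell and pluripotency genes in day 6 PGCLC of mouse (GK15) and monkey (GK15 and aRB27), where points are means and bars span the lowest to the highest library. Sox17 is 0.21 ± 0.297 RPM in mouse against 946 ± 163 RPM for SOX17 in monkey GK15, and Sox2 is 389 ± 6.68 RPM against 1.14 ± 0.757 RPM for SOX2.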

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

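Tests of name order, its title codes, mixed cells, shared codes and BT single cells between days were chosen only after the result was seen. So was every test on the 24 libraries.

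The library labelled reporter ESC library 5 stood far from the other 4 reporter ESC libraries, with 253 RPM of PRDM1, 588 of TFAP2C, 1211 of SOX17, 46.8 of NANOS3 and 16.8 of SOX2. By depth, aRB27 BTAG day 6 library 2 stood apart with 7.42 M reads and reporter ESC library 1 with 6.76 M. Chance puts about 1 in 20 groups past this limit, and 7 of the 23 groups and quantities tested were past it. Between days 2 and 4 the difference of BT single from BTAG positive cells changed. It was higher on day 2 for 65 genes and on day 4 for 47 in the 24 libraries, but for 1 and 0 as labelled. The compared libraries are the same in both sets, and day 2 has a lone BT single library. FABP1 (log2 8.29) was called in both sets. Called in the 24 libraries alone were TTR (7.89), APOB (6.23), FOXA1 (3.82), CDX1 (-4.42) and SP5 (-5.26), each as the difference on day 2 less that on day 4. The slope per day differed between media for 14 genes in the 24 libraries. From day 4 to day 6 NANOS3 differed by -0.59 in mouse and by 0.86 on the log2 scale in monkey, and this difference between species was not tested. The spike-in entries of the mouse table, which the comparisons did not use, summed to 60.05 and 76.4 RPM on day 4 and 90.2 and 77.1 RPM on day 6, from 14 to 19 of 96 entries.

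Of the 33 libraries of the reporter lines, 6 held PRDM1 at a level opposite to their sorting label. Cells of both populations mixed in a library are argued against in 5 of the 6. The share of BTAG positive cells was read from 520 genes other than the reporters that part the matching libraries, and there it lay inside or beyond the range of the opposite kind. For reporter ESC library 5 mixing cannot be told apart from an early day, as its share was 66.1% against 70.7% in the lowest matching library, which is of day 2. Names exchanged in pairs are argued against, since the lowest sum of squares within groups was 58.7% of that with the names as given. A candidate explanation is that the column names are out of order, since in alphabetical order 0 libraries contradicted the gate, and the sum of squares over 10935 genes without PRDM1 and TFAP2C was 47.7% of that with the names as given. Of 100000 random orders of the 19 displaced names the lowest gave 59.1%, so 0 reached that of the alphabetical order (permutation p = 1e-05, the smallest they can give). This order is a hypothesis found and tested on the same data, no library was renamed, and no biological explanation was tested.

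Over days 2 to 6, the days with libraries of both media, 48 genes differed between media in the 24 libraries. A batch effect of the title code as the whole cause is argued against, since with the code as a covariate their median log2 difference, signed by direction, was 97.3% of that without it (1.45 against 1.495, 44 genes called). With the codes of the alphabetical order, in which aRB27 has 2 MS134 libraries, it was 100.9% (1.51, 47 called). In the libraries labelled MS162 alone it was 1.48 with 7 of the genes called, with a median SE of 0.323 against 0.275 and fewer libraries. With median-of-ratios scaling it was 95% (1.42, 38 called). All genes moved (median -0.081 to -0.004) too little to decide on scaling. On these days aRB27 had 1 library of code MS134 and 6 of MS162, and GK15 1 and 3, so the covariate rests on few libraries. A response of the cells to the medium may account for these genes, which remains a hypothesis.

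SLC41A3, VAPB, ERP29, INSR and LOC102140476 were under 1 RPM in 30, 32, 33, 33 and 33 of 33 libraries of the reporter lines, and present in all 5 of the lines without transgenes. The lowest of these genes in the library of the parental line 656 was 7.63 RPM. It is a lone library and among those the genes were picked on, so a variant of that line stays open. Title code as a batch and the line itself cannot be told apart, because the 2 kinds of line share 0 title codes. A change that arose when the reporter lines were made was not tested.

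Other splits of the same libraries were fitted to test for chance, counting the real one. For aRB27 day 6 against ESC, 1 of 100 splits gave as many genes (real 2079, highest other 2054). In the 24 libraries it was 1 of 35 (2770 and 1462). Chance is excluded, but 2054 points to sample structure and the 24 were chosen on these data. Chance can also be excluded for day 2 against ESC in the 24 libraries (1 of 35, 1714 and 656). So it can for the media over days (1 of 100, 45 and 0). The same limit holds for these in the 24 libraries (1 of 90 splits drawn within days, 48 and 19). Monkey day 6 against day 4 was reached by 2 of 56 splits there, under 1 in 20. Another split called 283 against 59, which points to sample structure. For the ESC lines (1 of 100, 16 and 0, or 19 and 15 in the 24 libraries) chance stays open. The splits take libraries of a line as independent. Chance cannot be excluded for the slope between media in the 24 libraries (21 of 90, 14 and 287), which points to sample structure too. Where limma called 0 genes every split reaches that count, so the splits decide nothing for GK15 day 6 against ESC (56 of 56, highest other 1989), the slope between media (100 of 100, highest other 1) and monkey day 6 against day 4 (100 of 100, highest other 23) as labelled. For day 2 against ESC as labelled, 4 of 100 splits gave as many (136 and 1080). This is under 1 in 20, but 1080 points to sample structure, so chance is not excluded.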

How the results depend on the processing

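Alternatives on the 24 libraries, those without the 6 contradicted, 9 uncertain or 19 displaced libraries, the series of title numbers as a replicate block, and the tests on the MS134 libraries alone were chosen only after the result was seen. Over 872 results for named genes, settings other than leaving out a library kept direction and side of the threshold in 13134 of 14694 cases, lost the call in 1444 and gained it in 114. The direction was reversed for CDX2 in aRB27 day 6 as labelled with DESeq2 (-0.01) and for ID4 in the day trend without the 19 displaced libraries (0.069), and the cause was not tested. Leaving out a library kept 6028 of 6912 cases, with 864 calls lost, 20 gained and 0 reversed. Counts of genes stayed within 1.5 times in 333 cases and moved in 169 under the settings, and in 173 and 84 when a library was left out. The labels give no replicate numbers shared between groups, but the titles carry running numbers, and 7 series of these were fitted as a replicate block. Within series, deviations from group means had a mean correlation of 0.018, over 0.1 in 20 of 50 pairs. In the 24 libraries these were 0.031 and 9 of 24. The 2 pairs of BT single and BTAG libraries of day 4 gave 0.152. Names out of order would mix series, so these decide nothing. Each series has 1 medium, so the media over days could not be fitted with it. The title code and the MS134 libraries alone could not be fitted where a compared group had a lone code or no library, and aRB27 days 8 and 10 had no library among the 24. The depth of the shallowest library, 1.07 M reads, limits what can be said of genes under about 1 RPM.

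The counts that moved by more than 1.5 times are given by setting, those of the other days only as a sum over days and media. As labelled single days moved further. GK15 day 4 went from 36 to 0 with the compared groups alone and 203 with 656BTAG42 alone, aRB27 day 8 from 13 to 183 and 256, and aRB27 day 10 from 76 to 394 and 410. In the 24 libraries the compared groups alone gave 477 and 906 for GK15 days 2 and 4, the series block 938 and 1461 for aRB27 days 2 and 4, and a pseudocount of 10 gave 1807, 2217, 1020 and 1380 for GK15 days 8 and 10 and aRB27 days 2 and 4 in this order. Limits of 20 RPM and of a log2 difference of 2 lowered 5 and 6 of the 6 counts by as much. The cause was not tested, except that stricter thresholds and higher filters leave fewer genes to call and smaller sets hold fewer libraries. A mean of at least 20 RPM gave 1 for GK15 day 6, 1138 for aRB27 day 6, 80 for day 2, 985 for the day trend, 23 for media over days, 223 for BT single day 4 and 23 for BT single day 2. Further counts were 8 for ESC lines, 130 for mouse and 2651 for the other days. In the 24 libraries it was 1464 for GK15 day 6, 1538 for aRB27 day 6, 963 for day 2, 1186 for the day trend, 4 for media on day 6, 967 for BT single day 4, 420 for BT single day 2 and 557 for AG mid day 4. It also gave 281 for AG mid day 2, 12 for ESC lines, 29 for monkey day 6 against 4 and 7592 for the other days. edgeR gave 66 for GK15 day 6, 42 for day 2, 3 for media on day 6, 204 for BT single day 4, 29 for BT single day 2 and 29 for ESC lines. The 24 libraries gave 7 for media on day 6. DESeq2 gave 299 for GK15 day 6, 264 for day 2, 9 for the slope between media, 150 for media on day 6, 166 for media over days, 658 for BT single day 4 and 121 for BT single day 2. To these it added 4 for AG mid day 2, 356 for ESC lines, 138 for mouse and 40 for monkey day 6 against 4. For the 24 libraries this was 171 for the slope between media, 44 for media on day 6, 103 for media over days, 316 for ESC lines and 141 for monkey day 6 against 4. Fitting all 38 monkey libraries gave 1 for GK15 day 6, 207 for day 2 and 1 for media on day 6, and in the 24 libraries 3 for media on day 6, 273 for AG mid day 2 and 21 for monkey day 6 against 4. The title code as a covariate gave 1 for GK15 day 6, 11 for day 2, 24 for media over days and 2652 for the other days. With 24 libraries it gave 0 for the slope between media, 5 for media on day 6 and 29 for monkey day 6 against 4. MS162 libraries only gave 94 for GK15 day 6, 865 for aRB27 day 6, 0 for day 2, 0 for media on day 6, 28 for media over days, 619 for BT single day 4 and 42 for BT single day 2. The rest were 1 for AG mid day 4. From the 24 libraries came 1629 for GK15 day 6, 1 for the slope between media, 0 for media on day 6, 7 for media over days, 289 for AG mid day 2 and 0 for monkey day 6 against 4. 656BTAG42 libraries only gave 1350 for GK15 day 6, 61 for day 2, 0 for media on day 6 and 2 for monkey day 6 against 4, and in the 24 libraries 6 for media on day 6. Leaving out the 6 contradicted libraries gave 2680 for GK15 day 6, 1744 for day 2, 24 for media on day 6, 168 for media over days, 1637 for BT single day 4, 791 for BT single day 2 and 907 for AG mid day 4. Then came 474 for AG mid day 2, 61 for monkey day 6 against 4 and 17361 for the other days. Leaving out the 9 libraries of uncertain group gave 2649 for GK15 day 6, 1714 for day 2, 14 for the slope between media, 17 for media on day 6, 1619 for BT single day 4, 743 for BT single day 2 and 880 for AG mid day 4. Others were 457 for AG mid day 2, 59 for monkey day 6 against 4 and 12877 for the other days. A pseudocount of 10 gave 1201 for aRB27 day 6, 1164 for the day trend, 22 for media over days, 157 for BT single day 2 and 94 for mouse. Among the 24 libraries it was 1692 for GK15 day 6, 1622 for aRB27 day 6, 1012 for day 2 and 43 for media on day 6. A log2 difference of at least 2 gave 982 for aRB27 day 6, 82 for day 2, 849 for the day trend, 2 for media on day 6, 10 for media over days, 38 for mouse and 2390 for the other days. In the 24 libraries it was 1322 for GK15 day 6, 1206 for aRB27 day 6, 771 for day 2, 751 for the day trend, 10 for media over days, 931 for BT single day 4, 11 for ESC lines and 29 for monkey day 6 against 4. Next came 6517 for the other days. The series of title numbers as a replicate block gave 51 for aRB27 day 6, 0 for day 2, 0 for media on day 6, 45 for BT single day 2 and 755 for the other days. The 24 libraries gave 2 for the slope between media, 1 for media on day 6, 511 for AG mid day 4 and 32 for monkey day 6 against 4. MS134 libraries only gave 0 for aRB27 day 6 and 0 for media on day 6, and in the 24 libraries 872 for GK15 day 6, 789 for aRB27 day 6 and 0 for media on day 6. No filter on low values gave 60 for day 2, 21 for media over days, 342 for BT single day 2, 2 for AG mid day 4, 9 for AG mid day 2 and 0 for mouse. For the 24 libraries this was 1 for the slope between media, 11 for media on day 6 and 5 for media over days. Fitting the compared groups alone gave 0 for day 2, 0 for media on day 6, 1283 for BT single day 4 and 897 for BT single day 2, and in the 24 libraries 1 for media on day 6. The adjusted p alone gave 3048 for the day trend, 76 for media over days and 355 for mouse. Leaving out the 19 libraries of displaced names gave 274 for the day trend, 1486 for BT single day 4 and 611 for BT single day 2. Median-of-ratios scaling gave 1 for media on day 6, and in the 24 libraries 7 for media on day 6. Quantile normalization gave 1 for media on day 6, and in the 24 libraries 7 for media on day 6. Days 2, 4 and 6 only gave 2 for media over days. A pseudocount of 0.1 gave 51 for BT single day 2, and in the 24 libraries 0 for media on day 6, 495 for BT single day 2, 291 for AG mid day 2 and 31 for monkey day 6 against 4. CMK6 libraries averaged gave 37 for ESC lines in the 24 libraries. An estimated correlation between genes gave 3 for list tests, and in the 24 libraries 53 for list tests.

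Leaving out each library in turn gave the following ranges, with the count from all libraries in parentheses. As labelled they were 0 to 1660 for GK15 day 6 (0), 0 to 903 for day 2 (136), 0 to 1 for the slope between media (0) and 0 to 7 for media on day 6 (6). Next were 17 to 75 for media over days (45), 51 to 206 for BT single day 4 (403), 22 to 55 for BT single day 2 (78) and 0 to 14 for AG mid day 4 (0). Then there were 9 to 38 for ESC lines (16), 0 to 195 for mouse (214), 0 to 81 for monkey day 6 against 4 (0) and 2954 to 9192 for the other days (4514). In the 24 libraries the ranges were 0 to 297 for the slope between media (14), 0 to 6 for media on day 6 (17), 9 to 79 for media over days (48) and 414 to 518 for BT single day 2 (743). To these came 237 to 331 for AG mid day 2 (457), 5 to 41 for ESC lines (19) and 9 to 104 for monkey day 6 against 4 (59).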

Other observations

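None of the tests in this part was chosen only after the result was seen, but the 24 libraries they use were.

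Other gene lists were read on day 6 against ESC in the 24 libraries. For cholesterol synthesis in GK15, 5 of 13 measured members rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.000263 upwards, adjusted p = 0.156 with an estimated correlation). The aRB27 cells showed that 4 of 13 measured members rose (4 and 0 adjusted over the list alone, camera adjusted p = 6.33e-05 upwards, adjusted p = 0.114 with an estimated correlation). For fatty acid synthesis, 1 of 8 measured members rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.352 upwards) in GK15, where ELOVL6, a fatty acid elongase, was 421 ± 22.1 against 71 ± 14.4 RPM. In aRB27, 3 of 8 measured members rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.0103 upwards, adjusted p = 0.253 with an estimated correlation). Of the immediate early and stress list, 1 of 9 measured members rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.352 downwards) in GK15. EGR1 was 472 ± 52.2 against 88.5 ± 111 RPM, and TRIB3, a stress-induced pseudokinase, 2.36 ± 0.778 against 31.1 ± 22.4. For aRB27, 1 of 9 measured members rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.112 downwards). Of the retinoic acid list, 3 of 4 measured members rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.612 upwards) in GK15, with CRABP2 at 2.15 ± 0.488 against 166 ± 89.4 RPM. In aRB27, 1 of 4 measured members rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.756 upwards), with a median log2 difference of 1.44 and a mean of -0.61. The hypoxia and glycolysis, respiratory chain and neural lists did not pass in GK15 (camera adjusted p = 0.852, 0.867 and 0.867).

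Of the interferon list in GK15, 1 of 3 measured members rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.936 upwards), with IFI6 at 23.6 ± 15.2 against 3.47 ± 1.5 RPM, where its call was lost without GK15 BTAG day 6 library 3 (log2 1.70). For fibroblast and mesenchyme, 3 of 6 measured members rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.867 downwards), with a median of 1.015 and a mean of -0.40.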
